A study of Danio rerio with 32 samples.

How the data were processed

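Gene expression was measured with 1-colour Cy3 Agilent arrays in testes and brains of zebrafish labelled male, at 140 days post fertilization, after long exposure to dydrogesterone (DDG). There were 32 arrays on 8 slides. Each tissue had a solvent control group (SC) and groups exposed at a low (L), medium (M) or high (H) level, with 4 arrays per group. The labels give the order of the exposure levels and no concentrations.

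Total RNA was extracted with TRIzol, amplified and labelled with Cy3, per the labels' protocols. The scanner files hold a spot intensity that the authors' scanner software had background-subtracted and spatially detrended, per the file headers, with no scaling between arrays. The headers name version 11.5.1.1 of Agilent Feature Extraction, and the submitters' processing notes name version 10.7. The median pixel signal of each spot and of its local background was also deposited. The deposited value table is in log2 units, which no label describes. Set against the scanner files, each of its columns equalled the log2 intensity of its array minus that array's 75th percentile (largest deviation 4.99e-09, over 43553 probes with a single spot).

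The scanner files pair probes with accessions and not with symbols. Symbols came from the supplied RefSeq gene table, matched on the accession without its version. Of 43603 probes that are not controls, 26094 (59.8%) matched 1 gene each, giving 13443 genes, of which 7922 had more than 1 probe. Probes with no match stayed in every test as unnamed features. No sequence of the probes was aligned, so probes that bind near-identical paralogs could not be told apart from specific ones.

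The log2 intensity of each probe (its spots averaged) was set relative to the 75th percentile of its array. A probe was kept in a tissue when the scanner software called it well above background on at least 4 of the 16 arrays. For each named gene the probe with the highest mean over the 16 arrays was used, without regard to group. This left 28727 features in the testis and 26410 in the brain. Fits used limma 3.58.1 in R 4.3.3, with 1 mean per group over the 16 arrays of a tissue and the moderated test of each exposed group against SC. A feature was called at a Benjamini-Hochberg adjusted p under 0.05 over all features of the tissue. A moderated F test over the 3 contrasts and a linear trend over the 4 ordered groups were also run. Whether an exposed-minus-SC difference itself differed between tissues was tested in 1 fit to all 32 arrays, over 25895 features kept in both tissues, which also gave testis SC against brain SC as a check of the tissue labels.

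Lists of genes were written before the data were examined: 28 applied to the testis and 30 to the brain. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, where 5 or more members were measured, and adjusted over the lists of that tissue. The same test was run with an estimated correlation. Counts of members were made at the adjusted p over all features and adjusted over the list alone. Named genes were chosen by a rule fixed before the data were examined. It took up to 10 rises and 10 falls past the threshold in which the exposed and control arrays did not overlap. Where fewer than 10 passed, it took the 10 features with the smallest p. It also took up to 4 members with the smallest p of a discussed list. A fixed set of mostly reproductive genes, with some stress and clock genes, was added whatever their values. For length, some genes chosen by this rule, fixed ones among them, are not given below. Where all arrays of 1 group were below the background call, a fold is given as a bound against the background level of those arrays.

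Slide and array position were read from the names of the scanner files. In the brain, each of 4 slides held 1 replicate of all 4 groups, with SC always at position 1 and H at position 4. Brain results are therefore also given with the slide as a block and as differences within slides. In the testis, each slide held the 4 arrays of 1 group, so slide and group cannot be told apart there and no within-slide value exists. The replicate number in the testis is the position on the slide. The tissues were scanned on 2 different days.

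The tests were first run on simulated data with the real spread, sizes and group numbers. For the testis H comparison over 28727 features, 2.49% of 1.5-fold changes, 18.9% of 2-fold changes and 56.1% of 4-fold changes were recovered. For the brain H comparison over 26410 features, the shares were 17.4%, 37.3% and 67.2%. For the tissue difference of the H effect over 25895 features, they were 2.99%, 8.96% and 51.5%. A list shifted by -0.3 (log2) was called in 3 of 3 simulations in each of the testis M and brain M list tests, with 0 other lists called. The simulated genes were drawn independently, so this does not test false list calls among correlated genes. In splits of the real arrays, given below, the median number of lists called ran from 6 in testis H to 12 in brain L.

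Alternatives fixed beforehand were normexp background correction, quantile normalization, median centring, the authors' value table, 2 other filters on dim probes, 2 other ways of treating several probes per gene, other estimates of the spread, fold thresholds, a replicate block, a random slide effect, fits to 2 groups, other list tests, and leaving out each array in turn. Normexp used the median spot signal, because the files hold no mean signal. Leaving out 4 arrays that carried transcripts of another tissue was added after seeing the data. The comparisons of lists in either direction (limma's fry, mixed test) were also added then. No array was removed from the values reported first. The number of arrays limits the precision.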

Results

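The series asks how chronic exposure to dydrogesterone (DDG), a synthetic progestin used as a drug, changes the transcriptomes of testis and brain in zebrafish labelled male. Arrays were read at 140 days post fertilization, with 4 arrays in each of the groups SC, L, M and H of each tissue. Between 84.2% and 94.3% of the 43603 probes were well above background on the testis arrays, and between 73.6% and 95.7% on the brain arrays. The 75th percentile of the signal lay between 3723 and 5760 intensity units in the testis and between 1084 and 2092 in the brain, with 0 saturated spots on every array. All values below are log2 intensities relative to the 75th percentile of their array, and differences are exposed minus SC with their standard error (SE) from the limma fit, with n = 4 per group.

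The tissue labels were checked with the SC arrays. The germ cell gene sycp3, a part of the meiotic chromosome axis, was higher in testis than in brain by 7.41 (limma adjusted p = 7.19e-10), and the Leydig cell hormone gene insl3 by 7.34 (limma adjusted p = 4.47e-08). The astroglial filament gene gfap was lower in testis by -7.26, the synaptic gene snap25b by -8.17 and the brain aromatase gene cyp19a1b by -9.02 (the largest limma adjusted p of the 3 was 3.49e-15). Of 25895 features, 17210 differed between the tissues, 8608 higher in testis and 8602 higher in brain. All 17 measured genes of the meiosis list and 45 of 52 of the spermatid, sperm and axoneme list were higher in testis, while 35 of 41 of the synapse and neuron list and 13 of 15 of the myelin and oligodendrocyte list were higher in brain.

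In the brain of the H group, 2 genes of the circadian clock list and 3 of the heat shock list fell. The clock gene per1b, a light- and clock-driven repressor, was 4.17-fold lower (difference -2.06, SE 0.27, n = 4 per group, limma adjusted p = 0.0256), and cry5, a DNA photolyase of the cryptochrome family, was 3.13-fold lower (-1.65, SE 0.27, limma adjusted p = 0.0490). The inducible chaperone genes hsp70.3 and hsp70l fell by 1.07 (SE 0.14) and 1.08 (SE 0.17), and the heat shock transcription factor gene hsf2 fell by 0.92 (SE 0.15). The growth factor gene igf1 was 2.33-fold lower (-1.22, SE 0.17, limma adjusted p = 0.0256). Each of these genes was lower in H than in SC on 4 of 4 slides. Over all 26410 features, 19 were called, of which 15 fell and 4 rose. The 4 that rose carry no gene symbol, and 13 of the 15 that fell do. The falls without a symbol are probes of the same transcript. The largest rise was 4.53 (SE 0.62, limma adjusted p = 0.0256, and 0.0410 with the slide as a block). Its probe was very dim in SC, with a mean of -8.36. Among genes with a symbol, the other falls with the largest size were those of the cytochrome P450 gene cyp2ad6 (-1.76, SE 0.28), arhgef9b (-1.14, SE 0.19), the synaptotagmin gene syt13 (-0.98, SE 0.16) and the transcription factor gene etv5b (-0.93, SE 0.15). Of the 13 named genes, 7 had more than 1 probe, and in all 7 every probe moved the same way. With the slide as a block, 10 features were called, 6 of them among the 19. The blocked limma adjusted p was 0.0410 for per1b and for hsp70.3. It was above the threshold for cry5, igf1 and arhgef9b (0.0554), hsp70l and cyp2ad6 (0.0617), syt13 and etv5b (0.0890) and hsf2 (0.0952). Over the 22 alternatives for per1b, the adjusted p ran from 0.000513 to 0.201. Within slides, H minus SC for per1b ran from -2.46 to -1.15. The count fell to 0 when any array of the 2 groups other than SC replicate 4 was left out, and it was 18 without SC replicate 4. It was 47 without 4 doubted arrays described below, with all 19 among them.

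**Figure D1:**
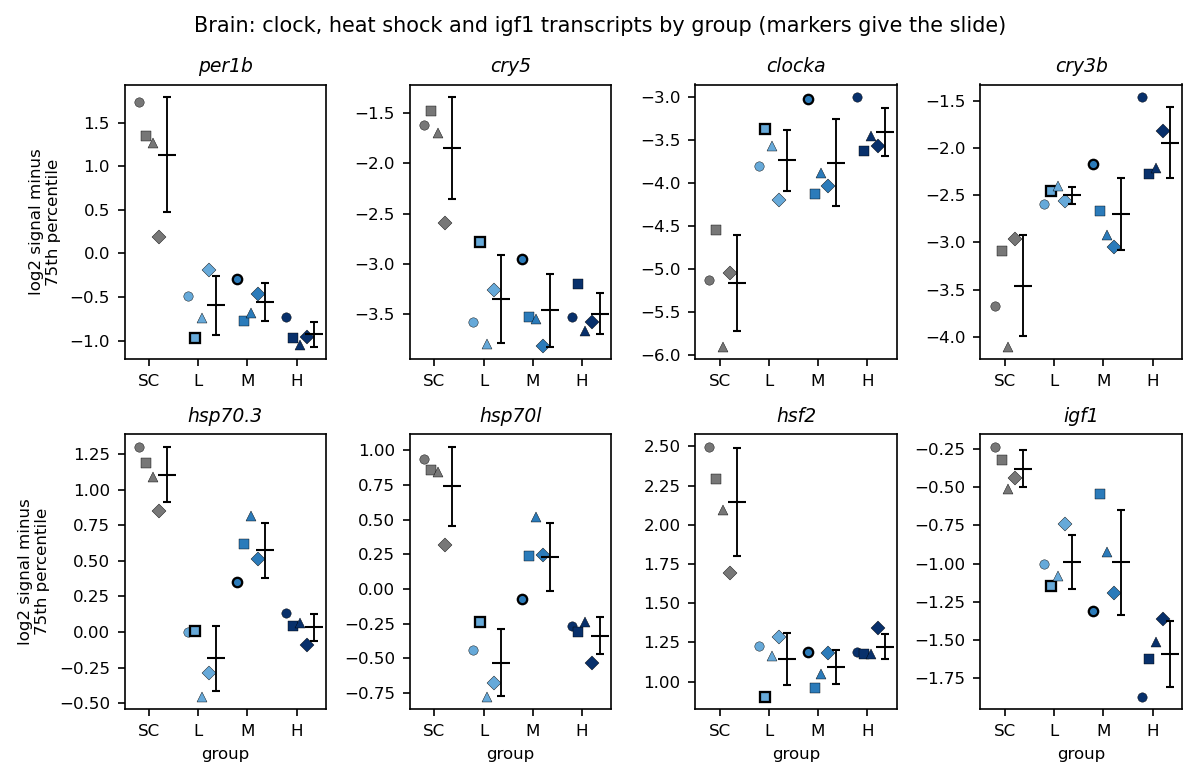
Log2 signal minus the array's 75th percentile (y axis) of 8 transcripts in the brain by group (x axis, SC, L, M and H). Points are single arrays, marker shapes are the 4 slides, a thick edge marks a doubted array, and the bar beside each group is the mean with 1 SD (n = 4). For per1b and hsf2 the 12 exposed arrays lie below all 4 SC arrays, and for clocka they lie above them.

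The list of circadian clock genes moved in both directions in the H brain. Over all genes, 2 of its 40 measured members fell and 0 rose. Adjusted over the list alone, 13 fell and 8 rose. The activator gene clocka was 1.74 higher (SE 0.30, limma adjusted p = 0.0587 over all features) and the cryptochrome gene cry3b was 1.52 higher (SE 0.26, adjusted p = 0.0594), each higher on 4 of 4 slides. As the members went both ways, the one-way list test gave a camera adjusted p of 0.0768 (adjusted p = 0.574 with an estimated correlation). A test of change in either direction, chosen after seeing the data, gave a fry adjusted p of 3.63e-10 and 1.38e-09 with the slide block. That test does not compare a list with other genes, and 12 of 30 lists passed it.

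The heat shock and chaperone list moved one way. Of 21 measured members, 20 were lower in H than in SC, with a median difference of -0.46. Over all genes 3 fell, and adjusted over the list alone 7 fell, among them hsp90aa1.2 (-0.54, SE 0.11, limma adjusted p = 0.104 over all features). The camera adjusted p was 8.79e-15, and the call held with an estimated correlation (adjusted p = 0.000269, and 0.00105 with the slide block). Within slides, the mean of the list differed by -0.47 to -0.44.

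Genes of cholesterol synthesis were lower together. All 25 measured members had a negative difference, with a median of -0.66. None passed over all genes, and adjusted over the list alone 13 fell, among them sqlea (-1.30, SE 0.28), msmo1 (-1.16, SE 0.31), lss (-1.14, SE 0.27) and the sterol sensor gene insig1 (-0.58, SE 0.13). The camera adjusted p was 4.02e-19 (adjusted p = 0.0593 with an estimated correlation, and 0.00845 with both an estimated correlation and the slide block). Within slides the mean of the list differed by -1.16 to -0.37. On SC replicate 3 the list mean stood 0.62 above the SC mean, while the other SC arrays lay between -0.27 and -0.14.

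Several other lists were called in the H brain at the preset correlation and lost with an estimated one. Cytosolic ribosomal protein genes were lower in 75 of 75 members (median -0.23, camera adjusted p = 5.45e-23, adjusted p = 0.203 with an estimated correlation). Oxidative phosphorylation genes were lower in 78 of 81 (median -0.21, camera adjusted p = 2.26e-19, adjusted p = 0.14 with an estimated correlation). Hypothalamic neuropeptide genes were lower in 29 of 34 (median -0.29, camera adjusted p = 1.29e-06, adjusted p = 0.14 with an estimated correlation), and the urotensin gene uts1 was the 1 member that fell over the list alone. Of 25 immediate early genes, which respond to neuronal activity, 6 fell and 1 rose over the list alone (camera adjusted p = 3.48e-05, adjusted p = 0.14 with an estimated correlation). The differences were -1.08 (SE 0.27) for both nr4a1 and klf4 and 0.40 (SE 0.12) for jun. Markers of tissues outside the brain moved as well. Pancreas and gut markers were lower in 19 of 24 (median -1.36, camera adjusted p = 6.57e-17, adjusted p = 0.078 with an estimated correlation), liver markers in 22 of 27 (median -0.65, camera adjusted p = 4.09e-13, adjusted p = 0.14 with an estimated correlation) and erythrocyte markers in 10 of 12 (median -0.40, camera adjusted p = 1.01e-05, adjusted p = 0.14 with an estimated correlation). Smaller shifts with a camera call were those of xenobiotic metabolism (0.000254), cell cycle (0.00236), radial glia (0.00545), myelin (0.015), skeletal muscle (0.0207) and reproductive neuroendocrine genes (0.0272). With an estimated correlation, the adjusted p of these 6 lay at 0.14, 0.603, 0.355, 0.509, 0.603 and 0.355. In all, 15 of 30 lists were called.

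Genes of the reproductive axis did not pass in the H brain. The difference was -0.23 (SE 0.17) for cyp19a1b, -0.65 (SE 0.25) for kiss2, -0.66 (SE 0.32) for kiss1, -0.31 (SE 0.28) for gnrh2 and 0.42 (SE 0.77) for gnrh3, with limma adjusted p values from 0.727 to 0.999. The pituitary hormone genes lhb (0.70, SE 2.23), cga (1.21, SE 2.12) and fshb (-0.00, SE 1.57) had errors larger than their differences. The androgen receptor gene ar differed by -0.12 (SE 0.16) and the estrogen receptor gene esr1 by 0.42 (SE 0.25). Among the steroid synthesis enzymes, hsd17b3, which makes testosterone from androstenedione, was lower by -0.96 (SE 0.19, limma adjusted p = 0.104), and it was the 1 of 20 members that fell over the list alone. The progesterone receptor gene pgr was not well above background on enough brain arrays to be tested.

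In the brain of the L group, 1 gene of the clock list and 3 of the heat shock list fell. The chaperone gene hsp70.3 was 2.44-fold lower (-1.29, SE 0.14, n = 4 per group, limma adjusted p = 0.01), hsp70l 2.41-fold lower (-1.27, SE 0.17) and hsf2 2-fold lower (-1.0, SE 0.15). The clock gene per1b was 3.31-fold lower (-1.73, SE 0.27) and cyp2ad6 3.55-fold lower (-1.83, SE 0.28), both at a limma adjusted p of 0.0452. The genes syt13 (-1.05), hccsa.1 (-0.80) and dynll1 (-0.76) also fell, and all 8 were lower than SC on 4 of 4 slides. Over all features 12 were called, of which 11 fell and 1 rose. The rise, of 3.89 (SE 0.62), was that of the unnamed probe that rose most in H. With the slide as a block 1 was called, hsp70.3 (limma adjusted p = 0.0475, and 0.00209 to 0.253 over its 22 alternatives). Leaving out 1 array at a time left 0 to 6 calls, with 0 without SC replicate 1, 2 or 3 or L replicate 4, 2 without L replicate 2, which carried oocyte transcripts (list mean 4.85 over SC), 4 without L replicate 3, 5 without L replicate 1 and 6 without SC replicate 4. Without the doubted arrays 9 were called, 4 of them among the 12.

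Of the clock list, 1 member fell over all genes in the L brain, and over the list alone 11 fell and 5 rose (camera adjusted p = 0.0446, adjusted p = 0.622 with an estimated correlation). The fry adjusted p for change in either direction was 3.72e-09. Of the heat shock list, 3 fell over all genes and 7 over the list alone (camera adjusted p = 8.16e-10, adjusted p = 0.00216 with an estimated correlation and 0.00694 with the slide block). Of 34 hypothalamic neuropeptide genes, 27 were lower and 11 fell over the list alone (camera adjusted p = 1.14e-09, adjusted p = 0.135 with an estimated correlation). The wake-promoting peptide gene hcrt differed by -1.27 (SE 0.24, limma adjusted p = 0.131 over all features), pdyn by -0.83 (SE 0.21) and nmba by -0.75 (SE 0.16). The kisspeptin gene kiss2 differed by -1.10 (SE 0.25, adjusted p = 0.225), and it was the 1 of 25 reproductive neuroendocrine genes that fell over the list alone. Cholesterol synthesis genes were lower in 22 of 25, with 9 falls over the list alone (camera adjusted p = 1.35e-10, adjusted p = 0.135 with an estimated correlation). Oxidative phosphorylation genes were lower in 77 of 81 (median -0.30, adjusted p = 0.135 with an estimated correlation), ribosomal protein genes in 75 of 75 (median -0.19, adjusted p = 0.385 with an estimated correlation) and pancreas and gut markers in 21 of 24 (median -1.10, adjusted p = 0.16 with an estimated correlation). Skeletal muscle markers were higher in 22 of 25 (median 1.04, camera adjusted p = 0.0023, adjusted p = 0.644 with an estimated correlation), with list means of 2.16 and 1.99 on L replicates 1 and 4 and -0.19 and -0.44 on replicates 2 and 3. In all, 16 of 30 lists were called, and 10 without SC replicate 2. The median of all features was 0.07 above SC.

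In the brain of the M group, clock genes were among the features with the smallest p, but 0 features passed in limma (smallest adjusted p 0.139), with 2860 at an unadjusted p under 0.05, of which 2008 were higher. Without SC replicate 4, 5 passed, and without M replicate 3, 1. The 5 named features with the smallest p were hsf2 (-1.05, SE 0.15), the DNA damage binding gene ddb2 (-1.54, SE 0.24), per1b (-1.69, SE 0.27), the light-induced clock gene per2 (-1.34, SE 0.23) and cry5 (-1.62, SE 0.27), each lower than SC on 4 of 4 slides. Over the list alone, 7 clock genes fell and 5 rose (fry adjusted p for change in either direction 7.39e-08), and 3 heat shock genes fell (camera adjusted p = 3.22e-06, adjusted p = 0.0169 with an estimated correlation). Lens crystallin genes were higher in 36 of 39 (median 0.84, camera adjusted p = 0.00186, adjusted p = 0.625 with an estimated correlation), and without the doubted arrays their camera adjusted p was 0.338. M replicate 1 carried transcripts of gonad genes. On it insl3 was 4.79 and sycp3 4.4 above the SC mean, and the spermatid, sperm and axoneme list and the oocyte and ovary list each stood 1.88 above it. The other lists called in M were ribosomal proteins, oxidative phosphorylation, pancreas and gut, and 10 more besides the clock, heat shock and lens lists, 16 in all, and each of them but heat shock was lost with an estimated correlation (smallest adjusted p 0.595). The median of all features was 0.11 above SC. The median over all probes was -2.07 on M replicate 1, while it lay between -2.83 and -2.72 on the other M arrays and between -2.76 and -2.63 on the SC arrays, so the rise and the excess of higher features are not shown for the group without that array.

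Over the 3 exposed brain groups together, the F test called 1 feature, hsp70.3 (limma adjusted p = 0.0432). It called 0 with the slide as a block, 9 without the doubted arrays, and 0 to 20 when 1 array was left out (20 without M replicate 1, 6 without SC replicate 4, 2 without M replicate 3, 0 without any other). The linear trend over the ordered groups called 0 in limma, with 1398 at an unadjusted p under 0.05 and per1b at the smallest adjusted p, 0.0936. It called 14 without M replicate 1, 6 without SC replicate 4, 2 without M replicate 2 and 1 without L replicate 4. Between the L and H brains, 0 of 40 clock genes and 0 of 21 heat shock genes differed in limma over all genes or over the list alone, with 1 of each list at an unadjusted p under 0.05. Between M and H, 1 gene of each list differed over the list alone. Between L and M, 3 heat shock genes and 0 clock genes did, with 4 and 5 at an unadjusted p under 0.05. The L and H calls shared 9 features, 8 lower and 1 higher, where independent lists of these sizes would share 0.00625 and 0.000151. Both use the same SC arrays, so these shares are not what would be found with no effect, and the overlap itself was not simulated. Across features the correlation of the L and H differences was 0.303 and their covariance 0.0593. Groups simulated with no effect gave 0.498 and 0.109. The simulation used the same spread in every group, with the doubted arrays included. With no effect, the covariance depends on the SC spread alone. The simulated values may therefore be too high, and they cannot show whether L and H agreed less than groups with no effect. With the controls split, the correlation of the L and H differences was -0.06.

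In the testis of the H group, 76 features were called and all 76 fell. The 8 with a gene symbol were dim. The gene cmn, which encodes calymmin, a protein of the notochord matrix, was 2.25-fold lower (-1.17, SE 0.13, n = 4 per group, limma adjusted p = 0.00158), with a second, dimmer probe at -0.29. The semaphorin gene sema7a was 2.2-fold lower (-1.14, SE 0.20, limma adjusted p = 0.0274) and the cell adhesion gene l1camb 2.31-fold lower (-1.21, SE 0.22, limma adjusted p = 0.0326). The vesicular glutamate transporter gene slc17a6b, lrp11 and the adrenergic receptor gene adrb2a were below background on all 4 H arrays. They were at least 1.2-fold, 1.98-fold and 1.04-fold lower (limma adjusted p = 0.00455, 0.00592 and 0.0469). The kinase gene guk1b fell by 0.87 (SE 0.15), while its other probe differed by 0.39. Of the 76 features, 74 were among the 7182 dimmest of the tested features and 35 were not well above background in one of the 2 groups. With normexp background correction 1 was called, and their median difference went from -1.45 to -0.62 with all 76 still negative. Leaving out 1 array at a time left 30 to 55 calls, with 30 without SC replicate 1, 36 without SC replicate 2 or H replicate 4, 37 without H replicate 1 or 3, 42 without SC replicate 4, 49 without H replicate 2 and 55 without SC replicate 3. The replicate block left 42. Without the doubted arrays 239 were called, 228 lower and 11 higher, with 75 of the 76 among them. Those arrays are in L and M, so the H and SC arrays stayed the same. Only the shared spread and the choice of tested features could change. The 4 H arrays share 1 slide, so slide and group cannot be told apart.

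**Figure D2:**
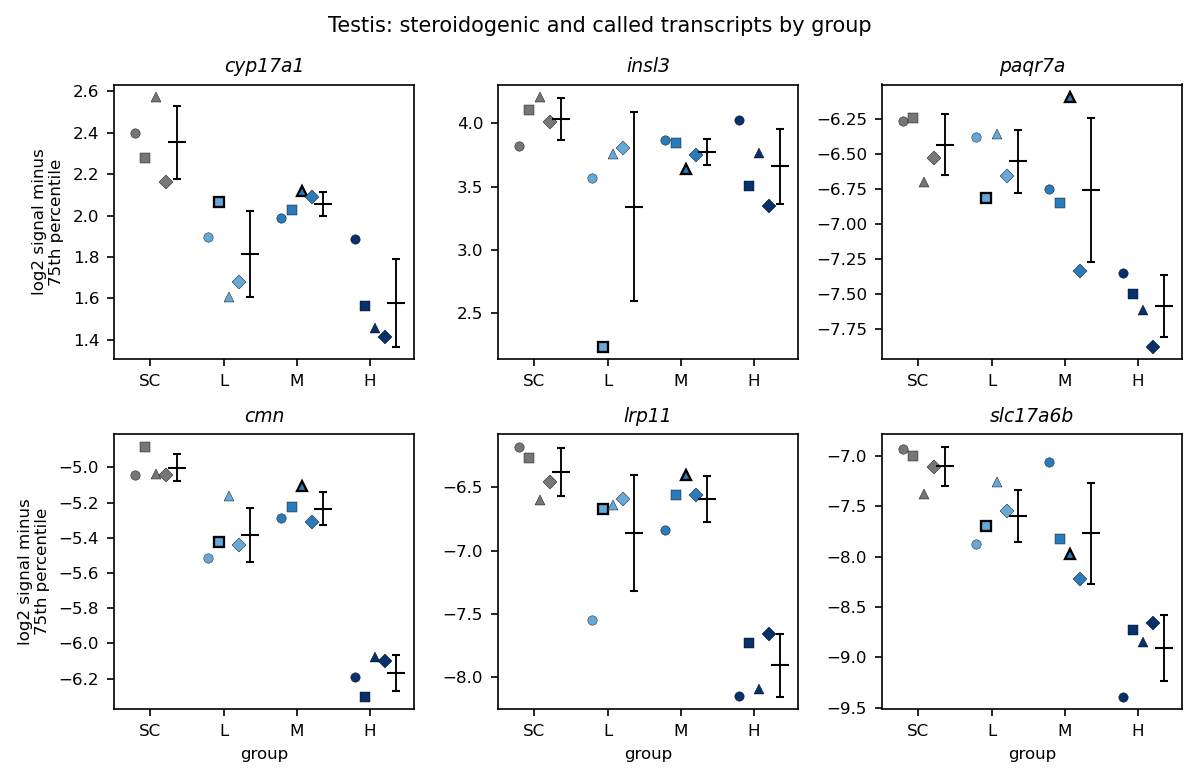
Log2 signal minus the array's 75th percentile (y axis) of 6 transcripts in the testis by group (x axis, SC, L, M and H). Points are single arrays, marker shapes are replicate numbers, a thick edge marks a doubted array, and the bar beside each group is the mean with 1 SD (n = 4). The 4 H arrays lie below the 4 SC arrays for cyp17a1, paqr7a, cmn, lrp11 and slc17a6b, and overlap with them for insl3.

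The steroidogenic gene cyp17a1, which encodes the enzyme that turns progestins into androgen precursors, was 1.71-fold lower in the H testis, with all 4 H arrays below all SC arrays. The difference was -0.77 (SE 0.16) and the limma adjusted p over all features was 0.0707, so it did not pass, but it was the 1 of 21 steroid synthesis genes that fell over the list alone. Its other probe was lower by -0.85. In L the difference was -0.54 and in M -0.30, each with an SE of 0.16. Without the doubted arrays the adjusted p for H was 0.0166, and over 21 alternatives it ran from 0.00289 to 0.447. The membrane progestin receptor gene paqr7a was below background on all 4 H arrays and at least 1.91-fold lower (limma adjusted p = 0.0666). It was the 1 of 18 steroid and gonadotropin receptor genes past the threshold over the list alone, where only the bound gives its size. Other genes of testis function did not pass in H. The difference was -0.38 (SE 0.29) for insl3, -0.32 (SE 0.46) for star, which moves cholesterol into mitochondria, -0.12 (SE 0.58) for cyp11c1, 0.22 (SE 0.58) for the Sertoli cell hormone gene amh, -0.22 (SE 0.20) for igf3, 0.05 (SE 0.41) for sycp3, -0.78 (SE 0.99) for lhcgr and 0.13 (SE 0.54) for fshr. The genes cyp11a1, hsd3b1, nanos2 and odf3b were not among the tested features.

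Of the 28 lists, 6 were called in the H testis, and none with an estimated correlation (each at an adjusted p of 0.987). Pancreas and gut markers were higher in 24 of 26 (median 0.76, camera adjusted p = 1.96e-07), with a list mean of 2.80 on H replicate 4 and -0.09 to 0.57 on the others. Skeletal muscle markers were higher in 23 of 25 (median 0.80, camera adjusted p = 0.000813), with list means from -0.61 to 2.15 on the H arrays. Ribosomal protein genes were lower in 69 of 75 (median -0.17), oxidative phosphorylation genes in 70 of 81 (median -0.13), cell cycle genes in 29 of 33 (median -0.15) and heat shock genes in 18 of 21 (median -0.21, camera adjusted p = 0.0199). No member of these lists passed. Without SC replicate 3, 2 lists were called, and without H replicate 2, 3. Among the lists not called were spermatid, sperm and axoneme genes (median -0.08, camera adjusted p = 0.755), meiosis (-0.05, 0.797), Sertoli cell (-0.01, 0.815), Leydig cell (-0.11, 0.563) and progestin and sperm maturation genes (-0.15, 0.334).

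In the testis of the L group, 0 features passed in limma (smallest adjusted p 0.436), with 2183 at an unadjusted p under 0.05, of which 1659 were lower. Egg coat and oocyte transcripts were far higher on the library labelled testis L replicate 2 than on any other testis array: zp3e, a gene of the egg coat, was at 4.31 there against an SC mean of -6.45 (SD 0.53), and 39 of 48 measured oocyte and ovary genes were highest on that array of all 16. On the same array the spermatid, sperm and axoneme list stood at -2.04 and insl3 at 2.23 against an SC mean of 4.04. Its median correlation with its group was 0.827, while the other 3 L arrays reached 0.965 to 0.968. The oocyte list was accordingly called in L (median 1.08, camera adjusted p = 1.73e-15, adjusted p = 0.848 with an estimated correlation), as were liver markers (median 0.90, camera adjusted p = 1.29e-07, adjusted p = 0.924 with an estimated correlation) and, lower, spermatid genes (median -0.61, camera adjusted p = 2.68e-05, adjusted p = 0.924 with an estimated correlation). Without SC replicate 1, 6 lists were called, and without L replicate 1, 5. Without L replicate 3, 1 feature was called, and without L replicate 4, 2. Without the doubted arrays 2 features were called, the oocyte median was 0.24 (camera adjusted p = 6.44e-06) and the spermatid median -0.06 (camera adjusted p = 0.192). Of the fixed genes, star differed by -1.16 (SE 0.46), insl3 by -0.70 (SE 0.29) and amh by -0.96 (SE 0.58), and without L replicate 2 and the other doubted arrays by -0.52, -0.33 and -0.11. The median of all features was -0.19 against SC. The median over all probes was -2.95 on L replicate 2, while it lay between -2.65 and -2.37 on the other L arrays and between -2.62 and -2.42 on the SC arrays.

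**Figure D3:**
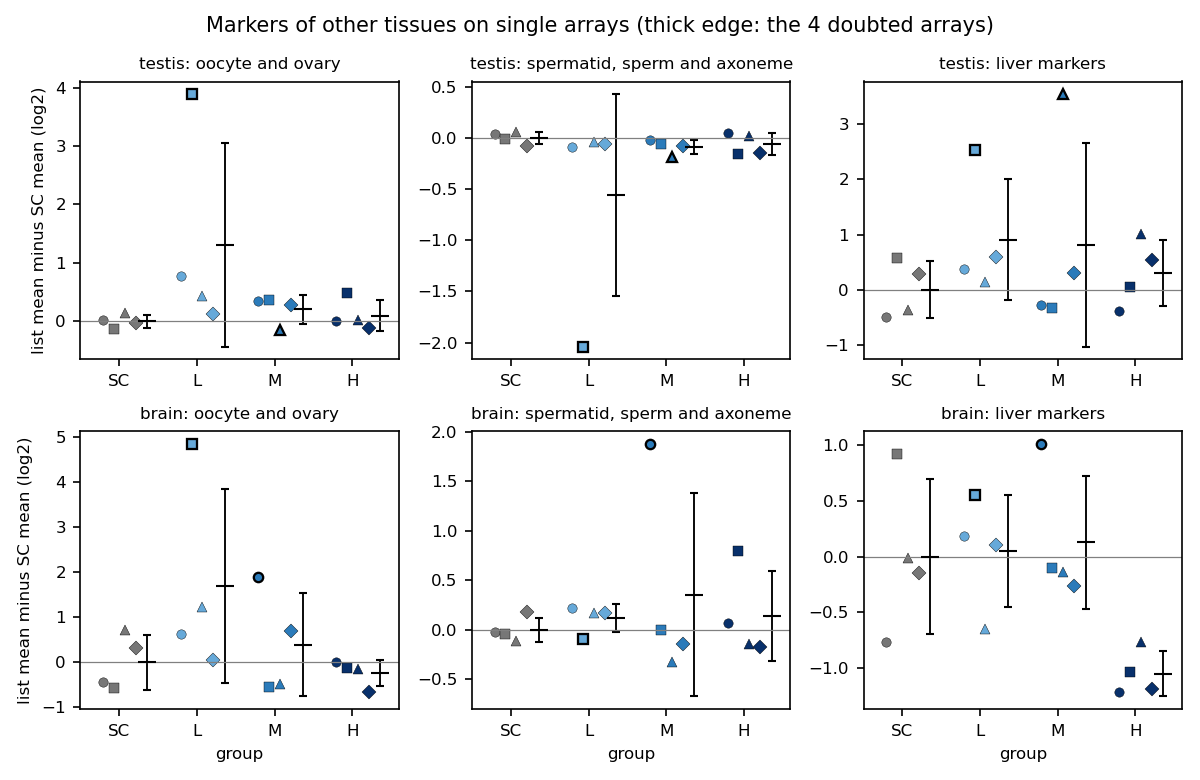
Mean of 3 gene lists on each array minus its SC mean in log2 units (y axis), in testis (top) and brain (bottom), by group (x axis). Points are single arrays, marker shapes are replicate numbers, a thick edge marks the 4 doubted arrays, and the bar is the group mean with 1 SD (n = 4). The oocyte list stands at 3.89 on testis L replicate 2 and 4.85 on brain L replicate 2, the liver list at 3.54 on testis M replicate 3 and the spermatid list at 1.88 on brain M replicate 1.

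In the testis of the M group, 0 features passed in limma (smallest adjusted p 1.0), with 588 at an unadjusted p under 0.05. The smallest p values belonged to tmem264 (1.49, SE 0.37), entpd8 (-1.07, SE 0.28) and nectin1b (1.28, SE 0.34). Of the 28 lists, 6 were called and none with an estimated correlation (adjusted p from 0.5 to 0.988). Liver markers were higher in 27 of 28 (median 0.85, camera adjusted p = 1.27e-06), but the list mean was 3.54 on M replicate 3 and -0.32 to 0.31 on the other M arrays, and without the doubted arrays the median was -0.18. Cell cycle genes were lower in 32 of 33 (median -0.17, camera adjusted p = 1.27e-06), ribosomal protein genes in 69 of 75 (median -0.12) and oxidative phosphorylation genes in 63 of 81 (median -0.10). Pancreas and gut markers (median 0.62) and skeletal muscle markers (median 0.54) were higher.

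The testis F test called 37 features and the trend 43, all of the latter with a negative slope over the ordered groups. Both named cmn, slc17a6b and lrp11, with limma adjusted p values for the trend of 0.00456, 0.00748 and 0.0182. A fall in H alone can give such a slope, and a fall at each step was not tested. Slide and group cannot be told apart in either test. Leaving out 1 array gave 17 to 108 trend calls, with 17 without SC replicate 2, 20 without SC replicate 1, 26 without H replicate 4, 28 without H replicate 1 and 108 without L replicate 2. For the F test the range was 5 to 85, with 5 without any 1 of the 4 H arrays, 8 without SC replicate 2, 9 without SC replicate 1, 11 without M replicate 2, 12 without SC replicate 4, 23 without M replicate 1 or 4 and 85 without L replicate 2. It was 1 in each test with normexp.

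No feature changed by an amount that differed between testis and brain at the adjusted threshold. The limma test of the difference itself called 0 of 25895 features at L, M and H, with smallest adjusted p values of 0.117, 0.166 and 0.0572 and 2680, 920 and 803 features at an unadjusted p under 0.05. Without the doubted arrays 9, 1 and 18 were called, and with a replicate block 0, 0 and 7. For L, 5 were called without brain SC replicate 4, 2 without testis L replicate 2, and 1 without testis SC replicate 2 or testis L replicate 3. For M, 2 were called without brain SC replicate 4 and 1 without brain SC replicate 3. For H, 3 were called without brain SC replicate 2, 2 without testis SC replicate 3 and 1 without brain SC replicate 4. For clock genes, the testis values in H were -0.50 (SE 0.19) for per1b, against -2.06 in brain, and -0.40 (SE 0.21) for cry5, against -1.65. Without the doubted arrays, which are in neither H nor SC, these testis differences were the same, with SEs of 0.107 and 0.145. Across the 40 clock genes measured in both tissues, the H differences of testis and brain had a correlation of 0.463 (across genes, which are not independent replicates). Of the heat shock genes, hsp70l differed by -0.18 (SE 0.19) and hsf2 by -0.27 (SE 0.16) in testis.

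**Figure D4:**
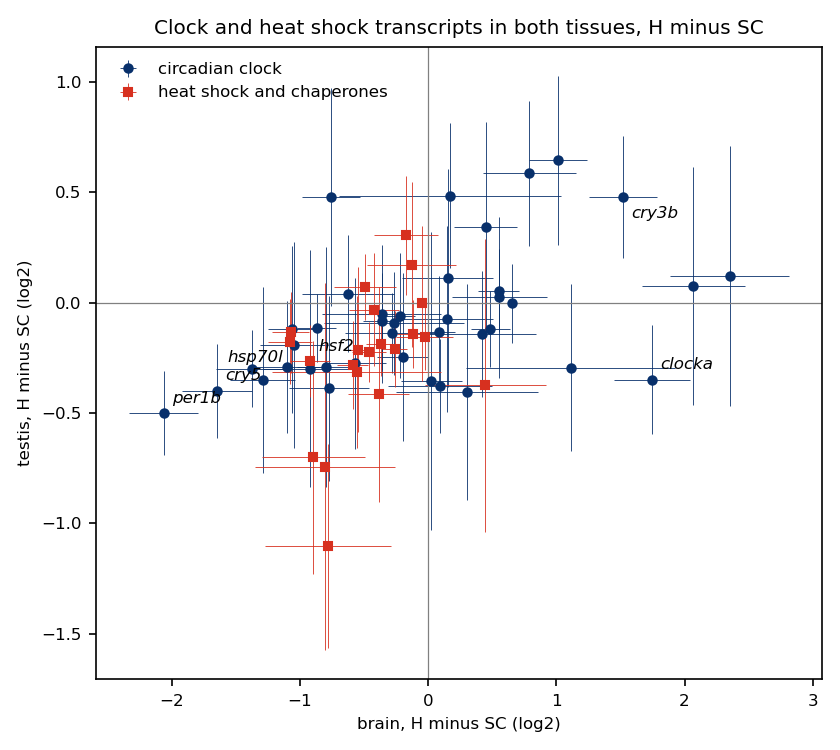
H minus SC in the brain (x axis, log2) against H minus SC in the testis (y axis, log2) for the genes of the circadian clock and heat shock lists measured in both tissues. Points are genes and bars 1 SE from limma (n = 4 per group). The clock gene per1b lies at -2.06 in brain and -0.50 in testis.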

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

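The tests on the array that carried oocyte transcripts, and the test of the share of neurons or glia, were chosen after the result was seen. The other tests were chosen before. An array was singled out when its gap to the nearest array of its group of 4 was most of the group's range. Chance does this in about 1 in 20 groups, and it happened in 34 of 256 groups, where 12.8 would be expected by chance. Of the 34, 9 fell on testis L replicate 2, 5 on brain M replicate 1 and 4 on testis M replicate 3. List means are given in log2 units over the SC mean of the tissue.

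The library labelled testis L replicate 2 had a median correlation of 0.8271 with its group. Its list means were low for interferon-stimulated genes (-2.143), erythrocyte markers (-2.06), spermatid, sperm and axoneme genes (-2.039), collagens and matrix (-1.996), progestin and sperm maturation (-1.354), Sertoli cell (-1.33), meiosis (-1.194) and the circadian clock (-0.8207). On testis M replicate 3 the correlation was 0.946, and the means were high for liver markers (3.543), xenobiotic metabolism (1.634) and the thyroid axis (1.36). On brain M replicate 1, 95.72% of probes were well above background, the correlation was 0.9032, and the means were high for liver markers (1.013), adipocyte markers (0.4933) and neurotransmitter systems (0.3108). Brain SC replicate 3 had a correlation of 0.9501 and a cholesterol synthesis mean of 0.6159.

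The other testis arrays that stood apart did so in 1 or 2 lists. Skeletal muscle was low on SC replicate 1 (-0.7459) and M replicate 2 (-0.345), and the clock list was high on M replicate 2 (0.08691). Collagens were low on M replicate 1 (-0.1619), ribosomal proteins on H replicate 2 (-0.356). Interferon-stimulated genes were high on H replicate 1 (0.2319), and progestin and sperm maturation genes on H replicate 4 (-0.02163) against its group. In the brain, cell cycle genes were high on L replicate 2 (1.917), pituitary hormones on L replicate 1 (1.639), retina and pineal genes on H replicate 1 (0.9047) and lens crystallins on SC replicate 2 (0.2937). Lens crystallins were low on H replicate 4 (-1.321), steroid and gonadotropin receptors on H replicate 4 (-0.2169) and immediate early genes on L replicate 4 (-0.1004).

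Oocyte transcripts stood out on testis L replicate 2. A small share of oocyte RNA added to testis RNA would leave testis transcripts near their level, but the spermatid list lay at -2.04 there. A noisy array would not raise 1 list together, but 81.25% of the measured oocyte genes were highest on it. An effect of the low exposure on all fish would appear at a like size on the other L arrays. Their median of the list was 0.44, against 3.89 on this array. The list was still called in L without the doubted arrays, as given above, so a smaller rise in L is not excluded. The other arrays cannot show an effect confined to 1 fish. Ovarian tissue in the fish that also gave brain L replicate 2 may be a source. The rises on both arrays had a correlation of 0.798 across the list, but other brain arrays reached 0.748, and no label ties the 2 libraries to 1 fish. Such tissue in the gonad would not by itself account for the brain library, where the list mean stood 4.85 above SC. A mislabelled or mixed sample cannot be told apart from this source.

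In the H testis, 74 of the 76 called features were among the 7182 dimmest of the tested features. A shift of all dim probes on the H slide is argued against by the median H-minus-SC difference of the 7182 dimmest tested features, 0.00026. The called features were dimmer still: the median of their mean log2 signals was -6.87, against -5.79 for the 7182. The median difference therefore cannot exclude a shift confined to the dimmest probes, and such a shift was not tested. A difference between slides stays open, since 0 testis slides hold more than 1 group, and an effect of exposure cannot be told apart from it. Of 35 splits of the 8 arrays into 4 and 4, 1 gave as many as 76, the real one, and the highest of the others gave 1. For the F test 1 of 100 drawn splits gave as many as 37 (highest other 1), and for the trend 1 of 100 gave as many as 43 (highest other 17). The real split alone is the smallest share that 35 splits can give, and several comparisons were made. These counts therefore make chance less likely without excluding it, and they do not bear on a slide effect.

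In the exposed brain, clock and heat shock transcripts differed from SC. Array position cannot be told apart from group on the brain slides. Over the 19 features called in H, the same 2 positions on testis slides differed by a median of -1.90% of the brain difference. Single features ran from -0.28 to 0.30 (log2). This argues against a position effect common to the slides of both tissues, and not against one on the brain slides alone. The positions of L and M were not checked. A loss of neurons or radial glia as large as the heat shock fall is argued against by the lower of the synapse and radial glia list means, -0.194, while the heat shock list moved by -0.46. A smaller loss, or a loss of other cell types or brain regions, was not tested. The time of sampling stays open as a cause, since a later or earlier time could move the clock list in both tissues. The H differences of brain and testis had a correlation of 0.463, which decides nothing by itself. In M the correlation was higher, at 0.698 (0.543 without the doubted arrays), and in L it was 0.149 (0.131 without them). An effect of exposure stays open too, and all 3 comparisons share the same 4 SC arrays. Of 35 splits, 1 gave as many as the 19 of H (highest other 10) and 1 as many as the 12 of L (highest other 2). Each was the real split, the smallest share that 35 splits can give. As several comparisons were made, chance is made less likely for a fit that ignores the slide and is not excluded. With the slide as a block the counts were 10 for H and 1 for L. No splits within slides were run, so the blocked counts were not tested against chance.

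For testis SC against brain SC, 1 of 35 splits, the real one, reached 17210 (highest other 14). A count of 0 is reached by every split, so the splits test nothing there: 35 of 35 splits reached the 0 of testis L (highest other 18), the 0 of testis M (highest other 1) and the 0 of brain M (highest other 6). The brain F test reached 1 in 9 of 100 splits (highest other 98) and the brain trend 0 in 100 of 100 (highest other 301). The tissue differences of L, M and H reached 0 in 100 of 100 splits each, with 13, 320 and 248 as the highest others. In the brain F test the highest split gave 98 calls, against 1 for the real grouping, and what set the splits with many calls apart was not tested. For the brain F test and the list calls the splits do not set the real count apart from chance. For list calls, as many as the real count came in 35 of 35 splits for testis L (real 3, highest other 12), 24 for testis M (6, 18), 19 for testis H (6, 11), 7 for brain L (16, 19), 3 for brain M (16, 17) and 6 for brain H (15, 16).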

How the results depend on the processing

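Leaving out the 4 doubted arrays was chosen after seeing the data; the other alternatives were chosen before. Among named genes called in the main fit or under an alternative, none reversed its direction under that alternative. Sign changes of genes called in neither fit were not counted. The authors' value table gave the same number of calls in each comparison as the scanner files, and for testis SC against brain SC the directions moved from 8608 higher and 8602 lower to 8603 and 8607. Unless said otherwise, the cause of a change was not tested.

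With normexp, run on the median signal because the files hold no mean signal, testis H had 1 call, the trend 1 and the F test 1, the brain F test 4 and the tissue difference of H 1. For testis H the 76 differences stayed negative and shrank from a median of -1.45 to -0.62. With quantile normalization testis H had 29, its F test 6, its lists 3, the brain trend 6 and the tissue difference of H 1. With median centring the testis trend had 66 and F test 21, brain L 6, M 1, H 8, trend 8 and F test 3, and the tissue difference of H 5.

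Keeping only probes well above background on all arrays, testis H had 13, the trend 10 and the F test 9. With no filter, brain L had 1, H 5 and the F test 0, and the tissue difference of H 9. With the mean of a gene's probes brain H had 7 and the F test 0, and with every probe on its own brain H had 10, the trend 1 and the F test 0. With an intensity trend and robust spread testis H had 25, the trend 14 and the F test 4, and the brain trend 9 and F test 17.

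Array quality weights gave more calls: testis L 1, M 232, H 1470, trend 570 and F test 1374, brain L 45, M 7, H 124, trend 60 and F test 78, and tissue differences of 15, 16 and 165 for L, M and H. With these weights 411 of the testis H calls were higher and 1059 lower, where all 76 were lower without them. Of the testis M calls 158 were higher and 74 lower. At an unadjusted p under 0.05 and 2-fold, testis L had 819, M 160, H 362, trend 0 and F test 613, brain L 395, M 570, H 266, trend 3 and F test 443, and the tissue differences 1554, 359 and 401. At an adjusted p under 0.05 and 2-fold the testis trend had 0 and brain H 12.

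With the replicate number as a block testis H had 42, its F test 7, brain L 1, H 10 and F test 0, and the tissue difference of H 7. The numbers pair arrays weakly: the correlation between same-numbered arrays of different groups had a median of 0.0186 in testis and 0.058 in brain. The blocked fit of testis SC against brain SC was not run, because the block is nested in the tissue. With the slide as a random block (correlation 0.137) brain L had 19, H 35, trend 5 and F test 13. Fitting only the 2 groups compared, testis H had 182 and brain L 0.

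Without the doubted arrays testis L had 2, H 239, trend 91 and F test 82, testis M lists 10, brain H 47, trend 12 and F test 9, and the tissue differences 9, 1 and 18. The H and SC arrays were the same in these fits. The H counts therefore moved through the shared spread or the features tested. With an estimated correlation the list calls were 0, 0 and 0 for testis L, M and H and 1, 1 and 1 for brain. With fry they were 0, 0 and 0, and 3, 1 and 3.

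Leaving out 1 array at a time gave 0 to 2 calls for testis L, 0 to 0 for M, 30 to 55 for H, 17 to 108 for the trend and 5 to 85 for the F test. In the brain it gave 0 to 6 for L, 0 to 5 for M, 0 to 18 for H, 0 to 14 for the trend and 0 to 20 for the F test. List calls ranged from 3 to 6, 4 to 8 and 2 to 7 in testis L, M and H, and from 10 to 18, 11 to 16 and 16 to 20 in brain. The tissue differences ranged from 0 to 5, 0 to 2 and 0 to 3, and testis SC against brain SC from 16194 to 16700.

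Signal over background limits the testis H result: 35 of its 76 features were not well above background in 1 of the groups. In brain the share of probes well above background ran from 73.6% to 95.7%.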

Other observations

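The probe that rose most in the brain H comparison has no gene symbol in the supplied table, and neither do the other 3 that rose, so their identity is not given here.

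On the library labelled brain L replicate 2 the oocyte list stood 4.85 above the SC mean, and the egg coat gene zp3e was at 2.56. On brain M replicate 1 the Sertoli and Leydig genes amh and insl3 stood 2.84 and 4.79 above the SC mean. No test of the source of the brain M replicate 1 transcripts was run.

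Across the 40 clock genes measured in both tissues, the exposed-minus-SC differences of brain and testis had a correlation of 0.149 in L and 0.698 in M, and of 0.131 and 0.543 without the doubted arrays.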
